A study of Mus musculus with 30 samples.

How the data were processed

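The data were 28 bulk RNA-seq libraries in 14 groups of n = 2 and 2 single-cell libraries from mouse hearts. Bulk groups were CFs cultured for 3 days from neonatal (postnatal day 1 to 3), 3-, 12- and 24-month animals, neonatal, 3-month and 18-month cells 3 days after LacZ or MGT, neonatal CFs with Nr4a3 overexpressed (OENr4a3) or a control (OECtrl) at day 10, and 3-month MGT cells with a hairpin against Nr4a3 or a non-targeting one (shNT) at day 7. The single cells were reprogrammed neonatal and 24-month cells. The labels do not say whether replicates were separate animals.

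The bulk files hold raw read counts per gene as deposited, in 4 tables that were scaled and tested separately. Per the submitters' processing notes, Trimmomatic 0.36, featureCounts from Subread 1.5.1, SAMtools and build mm10 were used. The aligner and the annotation are not stated. FPKM columns deposited beside the counts were not used. The single-cell files hold deposited whole-number counts per gene and barcode, made with a 10x Genomics kit per the labels and already filtered by barcode, since no barcode had fewer than 500 UMIs. Gene coordinates equalled those of the GRCm38 annotation used here for 99.4% of shared genes in the MGT table and 90.9% in the knockdown table, but for 2.8% and 2.9% in the CF and overexpression tables, so genes were joined by identifier or symbol and never by position. Some column names differ from the labels, which were followed. Columns named 13 months were taken as the 12-month samples, columns named 15 months as the 18-month samples, GFP as OECtrl and D3 as MGT. The labels give day 10 for the overexpression, where the design text gives day 7, and name both poly(A) RNA and rRNA depletion. Of the knockdown columns, 4 match no sample and were not used.

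Depth was 17.3 to 22.3M counts in the CF, 14.5 to 18.8M in the MGT, 14.3 to 18.4M in the overexpression and 39.7 to 43.4M in the knockdown libraries. The 10 most abundant genes held 5.29 to 9.13% of the counts of a library. At this depth 1 CPM is about 14 or more counts per library.

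Each table was fitted in R 4.3.3 with edgeR 4.0.16, with filterByExpr, TMM factors, 1 coefficient per group, estimated dispersions and a robust quasi-likelihood fit. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. The 17 planned comparisons were between ages of CFs, MGT against LacZ at each age, the 3 differences of the MGT effect between ages as interaction terms, between ages of MGT cells, and the overexpression and the knockdown each against its control. After the data were seen 2 comparisons between ages of LacZ cells were added. The 30 gene lists were fixed beforehand and tested with camera of limma 3.58.1 at a correlation of 0.01, for lists with at least 3 tested members, with p adjusted over the lists of a comparison. Sets of up to 200 genes with the smallest p in 1 table were tested in the others in the same way. Folds of genes with 0 counts in a group are bounds against 3 counts over the group, and for 1 to 3 counts an exact binomial interval of the ratio is given.

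Genes named in the text followed a rule written before the data were examined. It names Nr4a3 in every comparison, Mef2c, Gata4 and Tbx5 in those with MGT, and Cdkn1a, Cdkn2a, Cdkn2b and Mki67 in those of ages and of Nr4a3. It adds the 5 largest rises and 5 largest falls among called genes with an average log2 CPM of at least 3, no predicted-gene symbol and no overlap between the libraries of the groups (a condition left out for interactions), and up to 4 members of each described list with the smallest p. In single cells the members with the largest summed counts took the place of those with the smallest p, and the 5 rises and falls were taken from genes with at least 50 CPM and a 4-fold difference. The text uses a part of these genes, with preference for those whose call did not depend on a single library.

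Single cells were processed in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9 and scikit-learn 1.9.0. Barcodes with at least 500 genes and at most 20% mitochondrial counts were kept, which left 3828 of 4816 neonatal and 5773 of 6796 aged barcodes. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 50 components, 15 neighbours and Leiden clustering at resolution 0.5 gave 13 clusters. Components were computed in double precision. A cluster was named for a cell type when at least 3 of its markers were detected in 25% of cells and their median lay at least 2 log2 units above the other clusters, and left unnamed when at least 75% of the markers of another type were also detected. These names are rebuilt here and are not the authors'. A doublet score with Scrublet called 0 cells and did not work, so doublets were not removed. Summed CPM were compared between ages with exact Poisson and binomial 95% intervals, without a test, since each age had n = 1 library, and list medians use genes with at least 10 counts.

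Alternatives were RLE size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a replicate block, a fit to only the groups compared, each library left out, camera with an estimated correlation, and for single cells all barcodes, TMM scaling, a mean over cells, a minimum of 1000 genes, resolution 1.0 and thinning to 5000 UMIs. Single-gene results of 3 genes are not reported here and are left out of the counts over alternatives. A test for a sample that stands apart within a group was not run at n = 2. Replicates were compared by the chi-square of their counts against equal shares scaled to depth, over genes with at least 20 counts. The fits were tested on simulated data with the dispersions of each table. They recovered 65.7 to 83.6% of genes changed 2-fold with 3 to 16 false calls, and 1.5 to 5.0% of 200 random lists had a camera p under 0.05. The simulated genes were drawn independently of each other, so this share does not cover lists of genes that vary together. For single cells a list raised 2-fold reached percentile 100 among random lists, and 37 of 40 random lists lay between the percentiles 2.5 and 97.5.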

Results

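Cultured mouse cardiac fibroblasts (CFs) from hearts of different ages were compared with each other, after transduction with the cardiac reprogramming factors Mef2c, Gata4 and Tbx5 (MGT) or a LacZ control, and after the nuclear receptor gene Nr4a3 was overexpressed or, in MGT cells, knocked down with a short hairpin RNA. Every bulk group had n = 2 libraries and each age of single reprogrammed cells n = 1. In GRCm38 coordinates the manipulated genes were Nr4a3 (ENSMUSG00000028341, chromosome 4, 48045153 to 48086447, plus strand), Mef2c (ENSMUSG00000005583, chromosome 13, 83504034 to 83667080, plus strand), Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692, minus strand) and Tbx5 (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219, plus strand). Levels are given as mean ± SD of CPM (counts scaled to library size with TMM) over the libraries of a group, and changes as log2 fold change (log2FC) ± standard error. A gene was called when its edgeR adjusted p was under 0.05. The gene lists were fixed before the data were examined, and within a list "rose" and "fell" count the members called up and down with p adjusted over all genes. Counts "over the list alone" use p adjusted within the list. The p-values measure only the spread between these samples, as the labels do not say whether replicates were separate animals or cultures. No called list differed in sign between its median, its mean and its test. List calls used camera at a preset correlation between genes of 0.01, and fewer held when it was estimated. Those described here that held, in adult against neonatal CFs, were the fetal growth, senescence secretory and myofibroblast lists at every age, interferon-stimulated genes at 3 months, complement at 3 and 24 months and epicardial markers at 24 months. Among adult CFs, interferon-stimulated and fetal growth genes held for 12 against 3 months, and fetal growth and senescence secretory genes for 24 against 3 months. In MGT against LacZ cells the contractile, calcium, myofibroblast and epicardial lists held at every age, complement in neonatal cells and interferon-stimulated genes at 3 months, and of the differences between ages in the MGT effect only the epicardial list held, at both adult ages against neonatal cells. Across ages in MGT cells the fetal growth and myofibroblast lists held in all comparisons, the epicardial, endothelial, pericyte and senescence secretory lists against neonatal cells, and interferon-stimulated genes at 18 months against both other ages. No list call held in the Nr4a3 overexpression or knockdown. Replicate libraries differed more in some groups than in others. The chi-square per degree of freedom between them was 20.79 in 3-month LacZ, 16.96 in OECtrl, 13.28 in MGT+shNT and 26.52 in MGT+shNr4a3 cells and 2.35 to 7.29 in the other groups, and it rises with depth, which was highest in the knockdown libraries. The sex signal differed between groups of libraries. Xist, expressed from the inactive X of female cells, was at 1280 ± 7.82 CPM in neonatal and 804 ± 40.9 CPM in 24-month CFs but at 0.464 ± 0.0209 and 0.367 ± 0.114 CPM in 3- and 12-month CFs. It was at 532 ± 22.5 and 483 ± 61 CPM in neonatal LacZ and MGT cells and at most 0.54 ± 0.0398 CPM in adult ones. In OECtrl it was at 253 ± 41.2 CPM and in OENr4a3 at 484 ± 0.755 CPM. Y genes (CPM without TMM) were at 212 and 226 in OECtrl and 211 and 209 in OENr4a3, so they changed little while Xist rose. Neonatal CFs held Y reads too (49.9 and 50.4).

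Against neonatal CFs and after 3 days in culture, Mmp3, Cxcl5 and Ccl11 were among the genes with the largest rises in adult CFs. Mmp3, a secreted metalloproteinase, rose from 3.73 ± 0.106 CPM in neonatal cells to 3440 ± 93.8, 2900 ± 139 and 4960 ± 108 CPM at 3, 12 and 24 months (n = 2 per age), and the neutrophil chemokine gene Cxcl5 rose from 1.53 ± 0.571 CPM to 1350 ± 212, 2300 ± 28.7 and 2060 ± 259 CPM. Ccl11, an eosinophil chemokine gene without a read in neonatal cells, was at least 87-, 349- and 167-fold higher. These bounds were set against 3 counts over the neonatal group, and all floors and count intervals in this text cover counting error only. Both Mmp3 (log2FC 9.85 ± 0.068, 9.60 ± 0.068 and 10.375 ± 0.068, adjusted p at most 9.35e-41) and Cxcl5 (log2FC 9.81 ± 0.294, 10.59 ± 0.292 and 10.42 ± 0.292, adjusted p at most 8.21e-06) were called at each age. Of 16466 genes tested, edgeR called 8639 genes (4618 up, 4021 down) at 3 months, 9088 genes (4897 up, 4191 down) at 12 months and 8971 genes (4593 up, 4378 down) at 24 months against neonatal cells. Of 27 senescence secretory genes, 21, 18 and 20 rose and 5, 5 and 3 fell (21, 19 and 20 up with 5, 6 and 3 down over the list alone) at 3, 12 and 24 months, and the monocyte chemokine genes Ccl7 (log2FC 4.06 ± 0.058, 4.55 ± 0.057 and 4.42 ± 0.057, adjusted p at most 1.11e-32) and Ccl2 (log2FC 2.97 ± 0.049, 3.295 ± 0.049 and 3.14 ± 0.049, adjusted p at most 6.13e-31) were among those that rose. The list's median log2FC was 2.25, 1.95 and 2.48 (camera adjusted p = 1.66e-30, 7.7e-31 and 6.33e-34). Interferon-stimulated genes, which encode antiviral effectors and their regulators, were higher at every adult age, and of 25 members, 25 rose and 0 fell each time (the same over the list alone). Their median log2FC was 4.01, 2.56 and 3.48 (camera adjusted p = 4.16e-53, 6.35e-19 and 1.47e-36). The interferon list had adjusted p = 0.0328, 0.119 and 0.0508 with an estimated correlation, with examples in Isg15 (log2FC 4.565 ± 0.103, 3.10 ± 0.119 and 4.36 ± 0.104, adjusted p at most 6.44e-21) and Oasl2 (log2FC 3.84 ± 0.071, 2.585 ± 0.077 and 3.51 ± 0.072, adjusted p at most 4.02e-23). Of 10 complement genes, 9, 8 and 9 rose and 1 fell (the same over the list alone). The complement median was 3.235, 2.68 and 3.445 (camera adjusted p = 1.5e-28, 3.08e-21 and 9.11e-31). The complement list had adjusted p = 0.0328, 0.0632 and 0.0376 with an estimated correlation. Of 13 antigen presentation genes, 10, 12 and 12 rose and 0 fell (10, 13 and 13 up with 0 down over the list alone), including the class I gene H2-K1 (log2FC 2.36 ± 0.062, 1.98 ± 0.062 and 2.70 ± 0.062, adjusted p at most 3.96e-18). Their median was 1.76, 1.62 and 2.05 (camera adjusted p = 7.95e-10, 6.28e-07 and 1.61e-10). The antigen presentation list had adjusted p = 0.13, 0.155 and 0.105 with an estimated correlation. Of 16 NF-kappaB targets, 13, 11 and 12 rose and 2, 2 and 1 fell (13, 13 and 12 up with 2, 2 and 1 down over the list alone), and Sod2 (log2FC 2.04 ± 0.056, 2.78 ± 0.055 and 2.71 ± 0.055, adjusted p at most 7.11e-25) was one that rose. The NF-kappaB median was 1.17, 1.34 and 1.325 (camera adjusted p = 7.4e-06, 7.59e-08 and 4.32e-08). The NF-kappaB list had adjusted p = 0.13, 0.101 and 0.105 with an estimated correlation.

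Lower in adult than in neonatal CFs were fetal growth, myofibroblast, cardiac muscle, epicardial and endothelial genes. Cardiac troponin T (Tnnt2) fell from 764 ± 41.4 CPM in neonatal to 5.46 ± 0.541, 7.1 ± 1.39 and 4.84 ± 0.39 CPM in 3-, 12- and 24-month cells (n = 2 each). The imprinted RNA gene H19 (log2FC -6.48 ± 0.093, -8.22 ± 0.116 and -7.20 ± 0.101, adjusted p at most 1.44e-32) and the imprinted zinc finger gene Plagl1 (log2FC -4.12 ± 0.065, -5.43 ± 0.077 and -5.22 ± 0.073, adjusted p at most 1.61e-31) fell at every age. Of 16 fetal growth and imprinted genes, 1, 0 and 0 rose and 14, 16 and 15 fell (the same over the list alone) at 3, 12 and 24 months. Medians were -4.25, -4.67 and -4.965 (camera adjusted p = 1.42e-50, 4.54e-60 and 5.43e-57). Of 15 myofibroblast and TGF-beta genes, 1, 1 and 3 rose and 12, 13 and 11 fell (the same over the list alone). Medians were -1.75, -2.01 and -1.75 (camera adjusted p = 1.97e-20, 1.06e-25 and 2.56e-17). The smooth muscle actin gene Acta2 (log2FC -1.75 ± 0.042, -1.89 ± 0.042 and -1.75 ± 0.042, adjusted p at most 1.31e-26) and the periostin gene Postn (log2FC -3.465 ± 0.051, -3.40 ± 0.051 and -3.86 ± 0.052, adjusted p at most 6.83e-29) fell each time. Of 20 contractile genes, 0 rose and 20, 19 and 19 fell (the same over the list alone), with Tnnt2 (log2FC -7.13 ± 0.075, -6.76 ± 0.074 and -7.30 ± 0.077, adjusted p at most 6.83e-34) as an example and medians of -4.37, -3.004 and -3.73 (camera adjusted p = 3.67e-29, 8.21e-21 and 1.21e-21). The contractile list had adjusted p = 0.0594, 0.101 and 0.0856 with an estimated correlation. Of 17 calcium, channel and hormone genes, 2, 3 and 2 rose and 11, 12 and 11 fell (the same over the list alone), including the ryanodine receptor gene Ryr2 (log2FC -4.45 ± 0.261, -3.265 ± 0.231 and -3.71 ± 0.238, adjusted p at most 6.5e-14). The median of the calcium list was -1.91, -1.74 and -2.43 (camera adjusted p = 0.000509, 0.00549 and 0.0058). The calcium list had adjusted p = 0.13, 0.192 and 0.181 with an estimated correlation. All 10 epicardial and mesothelial markers fell at each age (the same over the list alone), such as Upk3b (log2FC -4.01 ± 0.202, -5.48 ± 0.253 and -5.25 ± 0.238, adjusted p at most 2.27e-17). Their median was -4.36, -6.685 and -6.50 (camera adjusted p = 6.29e-12, 1.2e-11 and 7.76e-12). The epicardial list had adjusted p = 0.0562, 0.0967 and 0.0446 with an estimated correlation. With members at 0 counts held at their bound this median was -4.36, -5.29 and -5.13. Of 12 endothelial markers, 2 rose and 8, 9 and 9 fell (2 and 9 over the list alone), with Emcn (log2FC -4.86 ± 0.081, -5.62 ± 0.091 and -5.33 ± 0.086, adjusted p at most 1.75e-30) having the smallest p. The endothelial median was -2.15, -2.94 and -2.98 (camera adjusted p = 6.08e-10, 2.32e-13 and 1.36e-12). The endothelial list had adjusted p = 0.13, 0.101 and 0.105 with an estimated correlation. Macrophage markers were lower by the test at 3 and 12 months only, and of 16 members, 2, 3 and 3 rose and 13, 11 and 12 fell (3 up with 13, 11 and 12 down over the list alone). The median was -1.32, -0.97 and -0.74 (camera adjusted p = 0.00019, 0.0261 and 0.0627). The macrophage list had adjusted p = 0.236, 0.492 and 0.543 with an estimated correlation.

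Nr4a3 itself was at 1.19 ± 0.562 CPM in neonatal and 2.25 ± 0.194, 4.3 ± 0.814 and 3.42 ± 0.136 CPM in 3-, 12- and 24-month CFs (n = 2 each). The log2FC against neonatal cells was 0.95 ± 0.302, adjusted p = 0.00868 at 3 months, 1.89 ± 0.276, adjusted p = 5.63e-07 at 12 months and 1.55 ± 0.282, adjusted p = 1.9e-05 at 24 months. The call at 3 months was lost without neonatal replicate 1 (log2FC 0.47, adjusted p = 0.285), without 3-month replicate 1 (log2FC 0.855, adjusted p = 0.0552) and with DESeq2 (log2FC 0.915, adjusted p = 0.0688), and without neonatal replicate 2 the log2FC was 1.46. Of the cell cycle inhibitor genes, Cdkn1a fell at 3 months (log2FC -0.38 ± 0.042, adjusted p = 1.75e-09) and rose at 12 and 24 months (log2FC 0.335 ± 0.041 and 0.25 ± 0.041, adjusted p = 2.38e-08 and 4.8e-06). At 24 months Cdkn2a (log2FC 1.77 ± 0.323, adjusted p = 2.1e-05) and Cdkn2b (log2FC 0.65 ± 0.147, adjusted p = 0.000307) rose as well, each from a low level. The proliferation list was higher at 3 months and lower at 24 months than in neonatal cells, and of 25 members, 24, 5 and 1 rose and 0, 10 and 16 fell (the same over the list alone) at 3, 12 and 24 months. Its median was 0.35, -0.16 and -0.31 (camera adjusted p = 0.00742, 0.433 and 0.0469). The proliferation list had adjusted p = 0.569, 0.917 and 0.666 with an estimated correlation. The cycling-cell marker Mki67 (log2FC -0.67 ± 0.059, adjusted p = 4.48e-09) fell at 24 months. Of 16 p53 targets, 1, 5 and 1 rose and 15, 6 and 9 fell (1, 5 and 1 up with 15, 7 and 9 down over the list alone). Medians were -0.52, 0.04 and -0.19 (camera adjusted p = 7.6e-05, 0.433 and 0.149). The p53 list had adjusted p = 0.194, 0.803 and 0.572 with an estimated correlation.

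**Figure D1:**
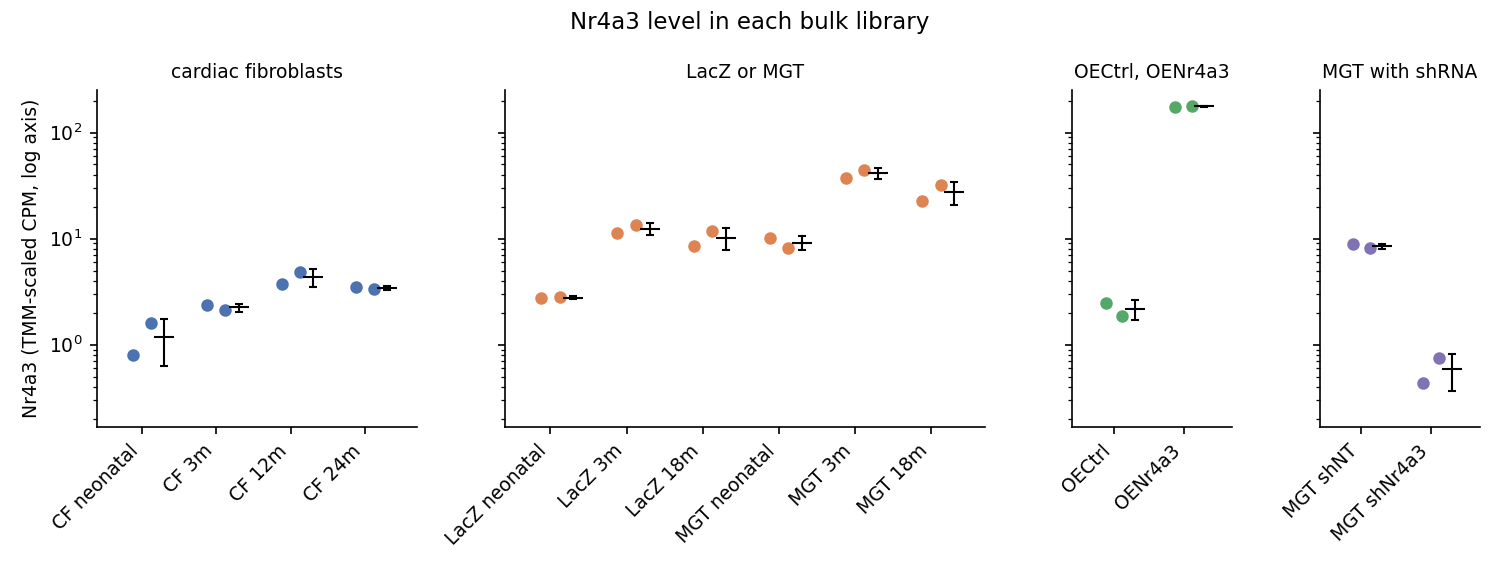
Nr4a3 level in every bulk library (TMM-scaled CPM, log axis). Points are libraries and bars are the mean ± SD of n = 2 per group. Each panel holds the libraries that were scaled together.

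Among adult CFs the oldest cells differed from 3-month cells in cell cycle, p53, glycolysis and imprinted genes. The interferon-stimulated genes were lowest at 12 months. Xist rose at 24 months (log2FC 10.74 against 3 and 11.05 against 12 months) and Eif2s3y of the Y chromosome fell (log2FC -1.84 against 12 months). Age and sex were not separated in these comparisons. Mki67 was at 279 ± 7.97 CPM at 3 months, 169 ± 10.1 CPM at 12 months and 147 ± 12.7 CPM at 24 months (n = 2 per age), and the cell cycle inhibitor gene Cdkn1a at 349 ± 2.59, 574 ± 19.5 and 541 ± 14.2 CPM. The collagen gene Col11a1 fell from 49 ± 0.85 CPM at 3 months to 6.78 ± 1.81 CPM at 12 and 4.53 ± 0.0411 CPM at 24 months, and the matrix gene Ltbp2 rose from 60 ± 1.14 to 218 ± 15.1 and 221 ± 2.17 CPM. Against 3 months these were Col11a1 (log2FC -2.83 ± 0.093 and -3.43 ± 0.098, adjusted p at most 5.01e-20) and Ltbp2 (log2FC 1.86 ± 0.051 and 1.88 ± 0.05, adjusted p at most 8.2e-23) at 12 and 24 months, with Mki67 (log2FC -0.72 ± 0.059 and -0.92 ± 0.059, adjusted p at most 6.89e-09) and Cdkn1a (log2FC 0.72 ± 0.042 and 0.63 ± 0.042, adjusted p at most 3.56e-13). Of 25 proliferation genes, 0 rose and 24, 25 and 10 fell (0 up with 24, 25 and 15 down over the list alone) in the comparisons of 12 with 3, 24 with 3 and 24 with 12 months, taken in this order throughout the paragraph. The median was -0.51, -0.73 and -0.20 (camera adjusted p = 1.36e-18, 7.37e-54 and 4.47e-05). The proliferation list gave adjusted p = 0.225, 0.109 and 0.542 with an estimated correlation. The kinetochore gene Cenpf (log2FC -0.80 ± 0.066 and -0.98 ± 0.066, adjusted p at most 1.99e-11) fell at 12 and 24 against 3 months. Of 16 p53 targets, 13, 13 and 1 rose and 1, 0 and 7 fell (14, 13 and 1 up with 1, 0 and 7 down over the list alone). The median was 0.45, 0.35 and -0.13 (camera adjusted p = 2.46e-14, 5.91e-13 and 0.0442). The p53 list gave adjusted p = 0.0783, 0.115 and 0.542 with an estimated correlation. Among the members was Ccng1 (log2FC 0.71 ± 0.042 and 0.47 ± 0.042, adjusted p at most 2e-10), a cyclin gene. Interferon-stimulated genes fell from 3 to 12 months and were higher again at 24 months. Of 25 members, 0, 1 and 22 rose and 25, 16 and 0 fell (0, 2 and 22 up with 25, 17 and 0 down over the list alone), and Isg15 was at 73.7 ± 1.25, 26.7 ± 2.57 and 64.1 ± 0.787 CPM at 3, 12 and 24 months. The interferon median was -1.46, -0.30 and 0.93 (camera adjusted p = 7.15e-73, 4.49e-11 and 9.29e-55). The interferon list gave adjusted p = 0.0251, 0.189 and 0.0695 with an estimated correlation. Of 10 complement genes, 1, 7 and 9 rose and 7, 1 and 0 fell (1, 8 and 9 up with 7, 1 and 0 down over the list alone). The median was -0.63, 0.44 and 0.87 (camera adjusted p = 1.99e-05, 1.96e-08 and 2.77e-28). The complement list gave adjusted p = 0.256, 0.167 and 0.0695 with an estimated correlation. The alternative pathway protease gene Cfb (log2FC 2.08 ± 0.139, adjusted p = 3.31e-13) rose from 12 to 24 months. Glycolysis and hypoxia genes were higher at 24 months than at both other ages, and of 23 members, 4, 17 and 16 rose and 5, 0 and 0 fell (4, 18 and 17 up with 5, 1 and 0 down over the list alone). Their median was -0.01, 0.53 and 0.50 (camera adjusted p = 0.739, 1.94e-23 and 7.22e-21). The glycolysis list had adjusted p = 0.934, 0.152 and 0.133 with an estimated correlation, and the pyruvate kinase gene Pkm (log2FC 0.57 ± 0.037, adjusted p = 3.57e-13) rose from 3 to 24 months.

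Fetal growth genes were lower at 12 and 24 than at 3 months, and of 16 members, 1, 0 and 3 rose and 12, 12 and 3 fell (1, 0 and 3 up with 12, 13 and 4 down over the list alone) in the same order of comparisons. Their median was -0.99, -0.86 and 0.11 (camera adjusted p = 5.27e-11, 4.68e-18 and 0.828). Examples were Rian (log2FC -0.77 ± 0.049 and -1.08 ± 0.05, adjusted p at most 5.5e-14) and Igf2bp2 (log2FC -0.91 ± 0.063 and -0.96 ± 0.062, adjusted p at most 3.21e-13). Of 27 senescence secretory genes, 11, 16 and 11 rose and 9, 4 and 6 fell (11, 19 and 12 up with 9, 4 and 6 down over the list alone). The median was 0.15, 0.365 and 0.105 (camera adjusted p = 0.141, 3.15e-09 and 0.000168). The senescence secretory list had adjusted p = 0.317, 0.0308 and 0.0749 with an estimated correlation. The metalloproteinase inhibitor gene Timp1 (log2FC 0.75 ± 0.044, adjusted p = 2.33e-14) rose from 3 to 24 months. Of 20 contractile genes, 12, 7 and 0 rose and 0, 0 and 2 fell (16, 10 and 0 up with 0, 0 and 2 down over the list alone). The median was 1.53, 0.94 and -0.26 (camera adjusted p = 1.99e-05, 0.000393 and 0.0861). The contractile list gave adjusted p = 0.317, 0.337 and 0.68 with an estimated correlation. The cardiac actin gene Actc1 was at 0.749 ± 0.296, 2.84 ± 1.34 and 2.83 ± 0.442 CPM at 3, 12 and 24 months. Of 16 macrophage markers, 7, 9 and 4 rose and 2, 0 and 1 fell (8, 12 and 4 up with 2, 0 and 1 down over the list alone). The median was 0.52, 0.605 and 0.07 (camera adjusted p = 0.0013, 1.96e-07 and 0.419). The macrophage list gave adjusted p = 0.336, 0.182 and 0.802 with an estimated correlation. Among these the lysozyme gene Lyz2 (log2FC 0.89 ± 0.062 and 0.705 ± 0.062, adjusted p at most 8.56e-09) rose in both comparisons with 3 months. The edgeR test called 4691 genes (2136 up, 2555 down) for 12 against 3 months, 3017 genes (1458 up, 1559 down) for 24 against 3 and 3110 genes (1781 up, 1329 down) for 24 against 12 months. DESeq2 called 3091, 1898 and 1971. Nr4a3 was higher at 12 than at 3 months (log2FC 0.94 ± 0.239, adjusted p = 0.00277), a call lost with DESeq2 (log2FC 0.94, adjusted p = 0.0506) and without 12-month replicate 2 (log2FC 0.73, adjusted p = 0.0916). It was not called at 24 against 3 months (log2FC 0.60 ± 0.243, adjusted p = 0.0859) or at 24 against 12 months (log2FC -0.34 ± 0.224, adjusted p = 0.34).

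At day 3 MGT cells expressed the transduced factors and cardiac muscle genes above LacZ cells at every age. The ryanodine receptor gene Ryr2 was at 25.9 ± 6.56, 14.2 ± 1.24 and 9.8 ± 0.282 CPM in neonatal, 3-month and 18-month MGT cells against 1.04 ± 0.107, 0.245 ± 0.106 and 0.387 ± 0.108 CPM in LacZ cells (n = 2 per group). Tnnt2 was at 1080 ± 281, 295 ± 26.2 and 251 ± 4.81 CPM against 286 ± 33.8, 2.91 ± 0.138 and 3.3 ± 1.15 CPM, so its level in MGT cells was lower at the adult ages while its distance from LacZ cells was wider. The factors, whose counts can include reads from the transgenes, rose at each age as Tbx5 (log2FC 6.78 ± 0.164, 8.15 ± 0.185 and 8.80 ± 0.198, adjusted p at most 2.34e-18), Mef2c (log2FC 3.51 ± 0.125, 4.44 ± 0.136 and 4.17 ± 0.136, adjusted p at most 1.75e-15) and Gata4 (log2FC 0.84 ± 0.088, 0.98 ± 0.089 and 1.06 ± 0.089, adjusted p at most 9.83e-08). Of 17 contractile genes, 12, 13 and 11 rose and 0 fell (13, 13 and 11 up with 0, 1 and 0 down over the list alone). Medians were 2.02, 3.41 and 3.22 (camera adjusted p = 5.52e-72, 1.35e-53 and 3.02e-66), the last being 3.13 with members at 0 counts held at their bound. Examples were the Z-disc gene Ldb3 (log2FC 2.26 ± 0.119, 3.41 ± 0.157 and 2.47 ± 0.13, adjusted p at most 4.02e-13) and the M-band gene Myom2 (log2FC 5.30 ± 0.199, 7.36 ± 0.247 and 6.40 ± 0.232, adjusted p at most 1.06e-11). The atrial light chain gene Myl7 had no read in 3-month LacZ cells and was at least 203-fold higher in MGT cells, and Actc1, with 1 to 3 LacZ counts, was higher at 3 months (323-fold, interval 89.1 to 2680) and 18 months (637-fold, interval 114 to 25200). Of 15 calcium, channel and hormone genes, 10, 11 and 7 rose and 0 fell (11, 12 and 9 up with 0 down over the list alone), including Ryr2 (log2FC 4.62 ± 0.236, 5.84 ± 0.329 and 4.63 ± 0.314, adjusted p at most 2.69e-11). The calcium median was 1.83, 3.295 and 1.435 (camera adjusted p = 6.69e-25, 2.75e-14 and 4.1e-12), and 1.39 at 18 months with bounds. Nr4a3 was at 9.15 ± 1.37, 41.1 ± 4.98 and 27.3 ± 6.7 CPM in MGT against 2.78 ± 0.0659, 12.4 ± 1.6 and 10.1 ± 2.37 CPM in LacZ cells, and rose at each age (log2FC 1.72 ± 0.234, 1.725 ± 0.172 and 1.43 ± 0.179, adjusted p = 2.15e-05, 1.25e-07 and 5.41e-06).

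**Figure D2:**
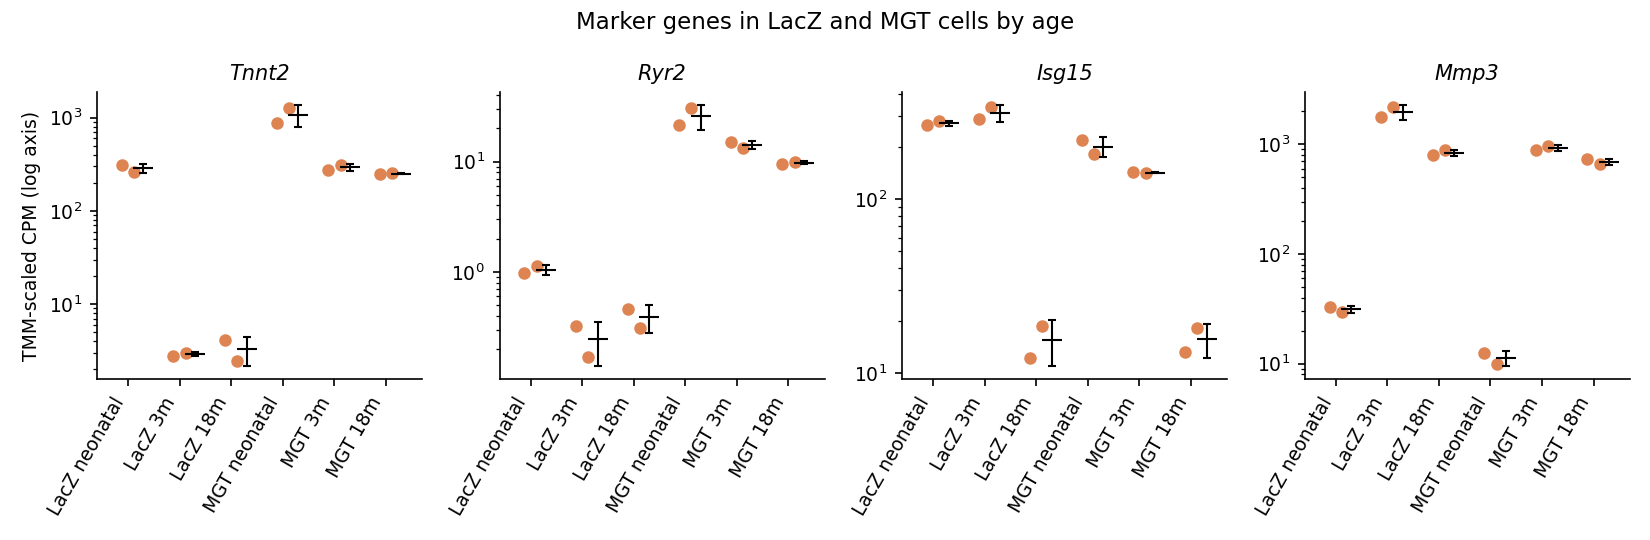
Tnnt2, Ryr2, Isg15 and Mmp3 in each LacZ and MGT library by age (TMM-scaled CPM, log axis). Points are libraries and bars are the mean ± SD of n = 2 per group.

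Apart from muscle genes, MGT cells had higher myofibroblast genes and, depending on age, lower interferon-stimulated, complement and proliferation genes than LacZ cells. Of 15 myofibroblast and TGF-beta genes, 8, 10 and 12 rose and 0, 1 and 0 fell (10, 10 and 12 up with 0, 1 and 0 down over the list alone) in neonatal, 3-month and 18-month cells. Medians were 0.43, 0.49 and 0.46 (camera adjusted p = 3.17e-12, 4.95e-11 and 3.05e-16), and the collagen modifier gene Cthrc1 (log2FC 1.90 ± 0.113, 2.63 ± 0.114 and 3.22 ± 0.133, adjusted p at most 5.26e-12) rose each time. Of 25 interferon-stimulated genes, 0 rose and 10, 24 and 2 fell (0 up with 19, 25 and 0 down over the list alone). The median was -0.51, -1.20 and -0.32 (camera adjusted p = 1.95e-13, 1.09e-40 and 0.0086). The interferon list came to adjusted p = 0.234, 0.0342 and 0.735 with an estimated correlation. At 3 months Ifit3 was at 70 ± 4.71 CPM in MGT and 526 ± 18.9 CPM in LacZ cells (log2FC -2.91 ± 0.255, adjusted p = 0.00018). Of 10 complement genes, 0, 1 and 3 rose and 7, 7 and 2 fell (0, 1 and 3 up with 9, 8 and 2 down over the list alone), with Serping1 (log2FC -0.92 ± 0.094 and -0.89 ± 0.093, adjusted p at most 7.31e-08) in neonatal and 3-month cells and a median of -0.78, -0.76 and 0.15 (camera adjusted p = 1.71e-09, 3.01e-05 and 0.903). The complement list came to adjusted p = 0.0398, 0.136 and 0.943 with an estimated correlation. Of 25 proliferation genes, 0 rose and 0, 12 and 23 fell (0 up with 0, 18 and 23 down over the list alone). The median was -0.12, -0.29 and -0.48 (camera adjusted p = 0.00792, 6.78e-05 and 7.07e-17). The proliferation list came to adjusted p = 0.584, 0.329 and 0.0653 with an estimated correlation. Among the members was Birc5 (log2FC -0.82 ± 0.1, adjusted p = 1.08e-06) at 18 months. Epicardial and mesothelial markers were lower in neonatal MGT cells and higher in adult ones, and of 10 members, 2, 5 and 4 rose and 6, 1 and 0 fell (2, 5 and 5 up with 6, 1 and 0 down over the list alone). Their median was -1.08, 1.56 and 0.74 (camera adjusted p = 2.44e-12, 1.67e-13 and 1.33e-11), or 1.07 and 0.64 at 3 and 18 months with bounds, and the mesothelial gene Msln (log2FC 5.37 ± 0.176 and 4.36 ± 0.17, adjusted p at most 5e-16) rose at both adult ages. Of 11 endothelial markers, 1, 3 and 3 rose and 1, 1 and 0 fell (1, 3 and 4 up with 1, 1 and 0 down over the list alone), with Flt1 (log2FC 5.26 ± 0.177 and 3.435 ± 0.184, adjusted p at most 2.34e-13) at the adult ages and a median of -0.25, 0.60 and 0.62 (camera adjusted p = 0.456, 0.000214 and 0.000847). The endothelial list gave adjusted p = 0.769, 0.181 and 0.235 with an estimated correlation. Of 14 macrophage markers, 0, 4 and 3 rose and 0 fell (0, 5 and 3 up over the list alone), with Csf1r (log2FC 1.15 ± 0.116 and 0.66 ± 0.11, adjusted p at most 0.000104) at the adult ages. Their median was -0.235, 0.31 and 0.20 (camera adjusted p = 0.228, 0.0424 and 0.191), or adjusted p = 0.765, 0.541 and 0.823 with an estimated correlation. The edgeR test called 1229 genes (698 up, 531 down) in neonatal, 2846 genes (1472 up, 1374 down) in 3-month and 2713 genes (1395 up, 1318 down) in 18-month cells. Without some single libraries each count changed more than 1.5-fold, as given below. A fit to only the groups compared called 1977 genes in neonatal and 1798 in 3-month cells.

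Whether the MGT effect differed between ages was tested as the difference itself. On the log2 scale it was larger in adult than in neonatal cells for several contractile and epicardial genes. For Tnnt2 the effect was larger at 3 months by a log2 difference of 4.74 ± 0.318 (adjusted p = 2.77e-05) and at 18 months by 4.32 ± 0.313 (adjusted p = 5.68e-05), with n = 2 per group. These effects are ratios to LacZ cells, where Tnnt2 was far higher in neonatal than in adult cells, as given above. Its level in MGT cells was lower at the adult ages, so a stronger response of adult cells does not follow from these differences. For the mesothelial gene Msln the differences were 5.35 ± 0.209 and 4.335 ± 0.201 (adjusted p = 1.48e-15 and 8.91e-14). Its LacZ levels were 124 ± 3.27, 0.881 ± 0.202 and 1.25 ± 0.277 CPM in neonatal, 3-month and 18-month cells and its adult MGT levels, 36.5 ± 0.109 and 26 ± 1.3 CPM, stayed below the neonatal control. For the matrix gene Abi3bp, in the other direction, they were -3.15 ± 0.377 and -3.87 ± 0.374 (adjusted p = 5.7e-06 and 2.79e-07). Of 10 epicardial markers, 5, 6 and 0 were called up and 0, 0 and 2 down (6, 6 and 1 up with 1, 1 and 3 down over the list alone) in the differences of 3 months from neonatal, 18 months from neonatal and 18 from 3 months. Medians were 2.82, 2.01 and -1.004 (camera adjusted p = 1.2e-33, 1.73e-28 and 0.085). Of 17 contractile genes, 5, 5 and 0 were called up and 0, 0 and 1 down (7, 6 and 0 up with 1, 0 and 1 down over the list alone). Medians were 0.95, 1.10 and -0.12 (camera adjusted p = 1.43e-13, 1.23e-13 and 0.8). The contractile list came to adjusted p = 0.132, 0.08 and 0.994 with an estimated correlation. Of 25 interferon-stimulated genes, 0, 1 and 8 were called up and 7, 0 and 0 down (0, 2 and 17 up with 20, 0 and 0 down over the list alone). Medians were -0.67, 0.13 and 0.84 (camera adjusted p = 1.44e-26, 0.0148 and 3.72e-39). The interferon list showed adjusted p = 0.132, 0.526 and 0.0943 with an estimated correlation, and the 3-month difference included Mx2 (log2FC -1.52 ± 0.246, adjusted p = 0.000979). Nr4a3 was not called for a difference between ages in its response to MGT (log2 differences 0.01 ± 0.406, -0.28 ± 0.299 and -0.29 ± 0.249, adjusted p = 0.999, 0.744 and 0.716). The edgeR interaction tests called 605 genes (374 up, 231 down), 461 genes (332 up, 129 down) and 383 genes (255 up, 128 down) in the same order. Each count changed more than 1.5-fold without some single libraries, as given below. The second was 882 in a fit to only the groups compared.

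Among MGT cells themselves, adult cells had higher secretory genes and lower contractile, fetal and epicardial genes than neonatal ones, and 18-month cells had lower interferon-stimulated genes than both other ages. Mmp3 was at 11.1 ± 1.72 CPM in neonatal, 928 ± 56 CPM in 3-month and 693 ± 47.5 CPM in 18-month MGT cells, and Ifi44 at 84.2 ± 3.32 CPM at 3 months and 4.16 ± 0.829 CPM at 18 months (n = 2 per group). Of 17 contractile genes, 1, 0 and 2 rose and 11, 11 and 1 fell (1, 1 and 2 up with 11, 12 and 1 down over the list alone) in the comparisons of 3 months with neonatal, 18 months with neonatal and 18 with 3 months. Medians were -1.32, -1.35 and -0.03 (camera adjusted p = 1.3e-08, 1.15e-06 and 0.636). The contractile list showed adjusted p = 0.12, 0.21 and 0.871 with an estimated correlation. The M-band gene Myom1 (log2FC -2.71 ± 0.168 and -1.22 ± 0.15, adjusted p at most 8.44e-07) fell at both adult ages, and the alpha myosin gene Myh6, without a read in 3-month MGT cells, was at least 82.5-fold lower there. Of 25 interferon-stimulated genes, 0 rose and 13, 25 and 23 fell (0 up with 17, 25 and 23 down over the list alone). Medians were -0.545, -3.36 and -2.61 (camera adjusted p = 9.02e-07, 8.93e-82 and 1.41e-125). The interferon list reached adjusted p = 0.308, 0.01 and 0.0113 with an estimated correlation. Among the members was Bst2 (log2FC -3.325 ± 0.117 and -3.12 ± 0.117, adjusted p at most 1.59e-14) at 18 months against neonatal and 3-month cells. Of 16 fetal growth genes, 0 rose and 15, 15 and 4 fell (the same over the list alone). Medians were -1.405, -2.09 and -0.38 (camera adjusted p = 5.08e-26, 4.45e-33 and 0.000596). Among the members was Mest (log2FC -4.59 ± 0.195 and -4.69 ± 0.196, adjusted p at most 8.42e-16) against neonatal cells. Of 10 epicardial markers, 0, 0 and 1 rose and 9, 8 and 1 fell (1, 0 and 2 up with 9, 9 and 2 down over the list alone). Medians were -3.23, -2.14 and -0.29 (camera adjusted p = 5.88e-24, 8.32e-23 and 0.584), or -2.11 at 3 months with bounds. Of 11 endothelial markers, 0, 1 and 1 rose and 8, 8 and 2 fell (0, 2 and 1 up with 8, 8 and 4 down over the list alone). Medians were -2.44, -2.87 and -0.63 (camera adjusted p = 2.46e-19, 8.4e-21 and 0.0368). The endothelial list came to adjusted p = 0.00705, 0.01 and 0.41 with an estimated correlation. Of 14 macrophage markers, 11, 10 and 0 rose and 2, 3 and 2 fell (11, 11 and 0 up with 3, 3 and 2 down over the list alone). Medians were 1.03, 1.005 and -0.06 (camera adjusted p = 2.72e-05, 0.000591 and 0.636). The macrophage list came to adjusted p = 0.19, 0.271 and 0.871 with an estimated correlation. Of 31 senescence secretory genes, 25, 19 and 5 rose and 3, 5 and 17 fell (25, 22 and 6 up with 3, 5 and 19 down over the list alone). Medians were 1.675, 1.005 and -0.67 (camera adjusted p = 1.76e-27, 4.65e-13 and 7.93e-06). The senescence secretory list gave adjusted p = 0.0044, 0.0222 and 0.099 with an estimated correlation. Of 15 myofibroblast genes, 2, 1 and 9 rose and 11, 10 and 1 fell (3, 1 and 9 up with 11, 10 and 1 down over the list alone). Medians were -1.13, -0.37 and 0.40 (camera adjusted p = 2.06e-16, 5.66e-05 and 1.85e-07), where Postn (log2FC -3.60 ± 0.101 and -3.62 ± 0.101, adjusted p at most 2.38e-19) fell against neonatal cells and Actg2 (log2FC 2.26 ± 0.188, adjusted p = 1.97e-09) rose from 3 to 18 months. Of 8 pericyte and smooth muscle markers, 2, 1 and 3 rose and 6, 4 and 2 fell (2, 1 and 3 up with 6, 5 and 2 down over the list alone) for 3 months against neonatal, 18 months against neonatal and 18 against 3 months. Medians were -1.75, -1.26 and 0.55 (camera adjusted p = 3.48e-11, 2.13e-05 and 0.00459). The pericyte list had adjusted p = 0.00594, 0.0452 and 0.113 with an estimated correlation, and the smooth muscle myosin gene Myh11 (log2FC 2.72 ± 0.217, adjusted p = 9.72e-10) rose from 3 to 18 months.

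In these MGT cells Nr4a3 rose from neonatal to 3-month (log2FC 2.16 ± 0.178, adjusted p = 3.67e-09) and 18-month cells (log2FC 1.575 ± 0.18, adjusted p = 4.9e-07), with n = 2 per age. It was lower at 18 than at 3 months (log2FC -0.59 ± 0.161, adjusted p = 0.0137), a call lost without 3-month replicate 2 (log2FC -0.465, adjusted p = 0.174) and without 18-month replicate 1 (log2FC -0.34, adjusted p = 0.232). The 3 factors were not called as a list. Medians were 0.06, -0.27 and -0.07 (camera adjusted p = 0.946, 0.672 and 0.584), where 0 rose and 1 fell each time (0 up with 1, 2 and 1 down over the list alone). The test called 4264 genes (2050 up, 2214 down) for 3 months against neonatal, 5003 genes (2351 up, 2652 down) for 18 months against neonatal and 2850 genes (1329 up, 1521 down) for 18 against 3 months. Without 3-month replicate 2 the first count was 2758, and without 3-month replicate 1, 3-month replicate 2 or 18-month replicate 2 the third was 1763, 1367 and 1589.

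**Figure D3:**
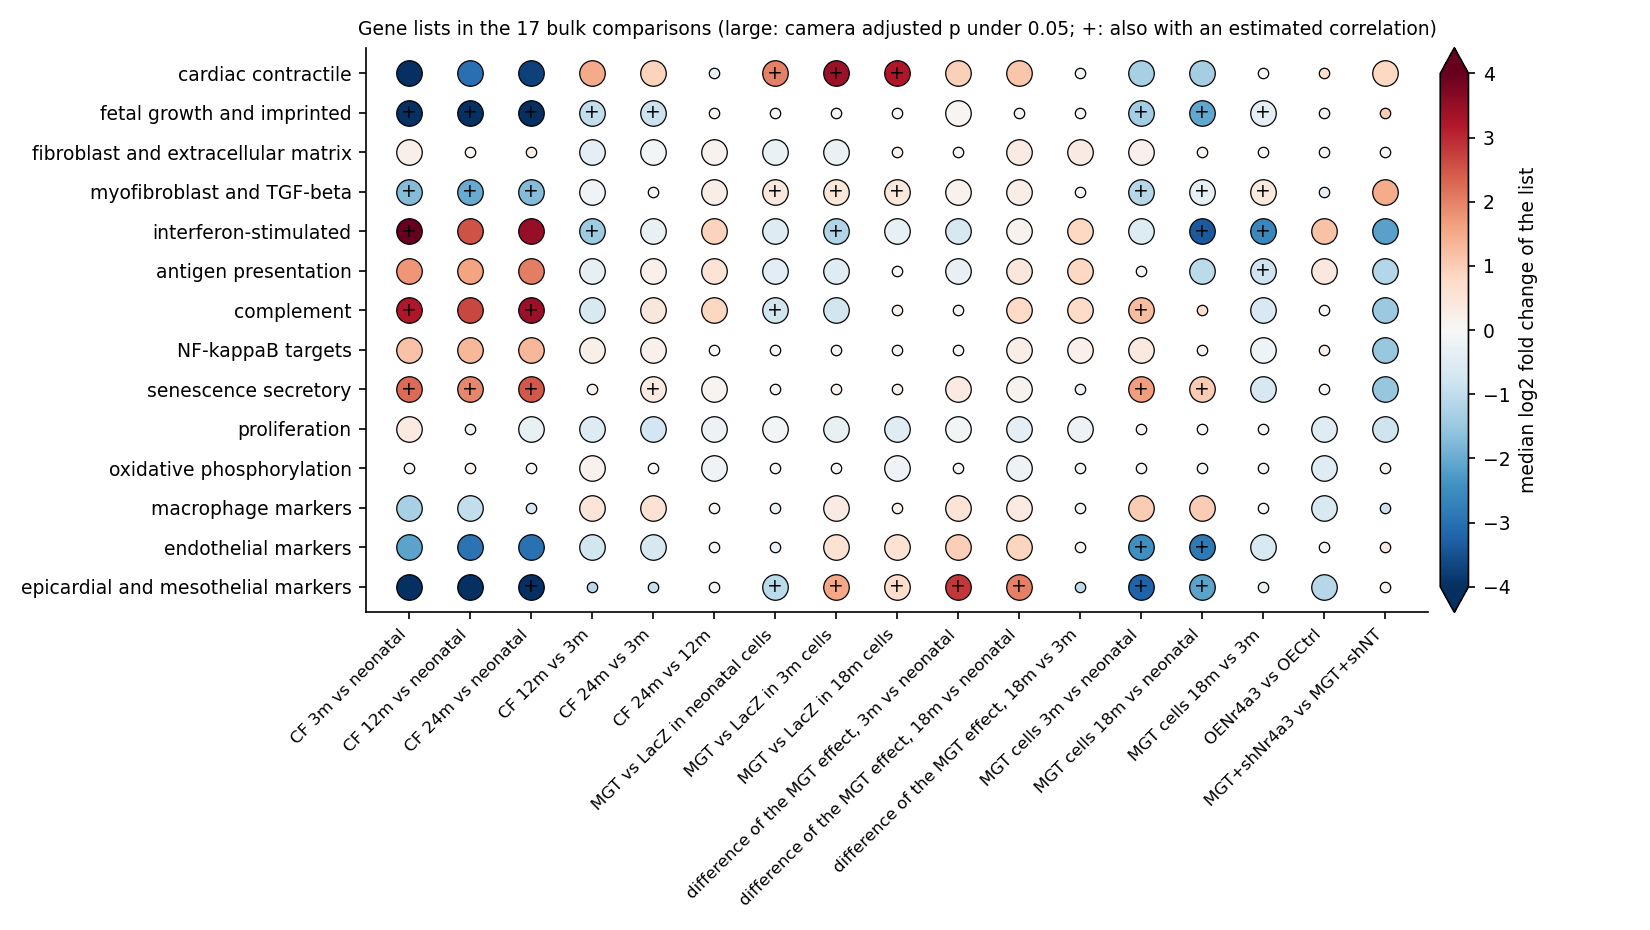
Median log2 fold change of 14 gene lists in the 17 planned bulk comparisons (colour). Large points are lists with a camera adjusted p under 0.05, and a plus marks those also called with an estimated correlation.

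With Nr4a3 overexpressed in neonatal CFs, at day 10, Nr4a3 was at 177 ± 1.72 CPM against 2.17 ± 0.45 CPM in controls (log2FC 6.35 ± 0.158, adjusted p = 1.28e-07), a count that can include the introduced copy (n = 2 per group). Interferon-stimulated genes were higher and oxidative phosphorylation, proliferation, epicardial and macrophage genes lower in OENr4a3 cells. Among the largest rises was the secreted adipokine gene Ccdc3 (105 ± 5.36 against 0.725 ± 0.243 CPM, log2FC 7.14 ± 0.191, adjusted p = 1.3e-07), and the hormone gene Rln3, with 2 control counts, was higher as well (980-fold, interval 271 to 8100). The potassium channel gene Kcna5 (log2FC 5.39 ± 0.199, adjusted p = 1.21e-06) rose, and the prostaglandin dehydrogenase gene Hpgd (8.47 ± 0.801 against 60 ± 7.63 CPM, log2FC -2.825 ± 0.148, adjusted p = 1.24e-05) and the growth factor binding gene Igfbp4 (log2FC -2.39 ± 0.12, adjusted p = 1.04e-05) fell. Of 23 interferon-stimulated genes, 17 rose and 0 fell (21 and 0 over the list alone). The median was 1.185 (camera adjusted p = 1.78e-17), or adjusted p = 0.481 with an estimated correlation. Among the genes that rose were Oasl2 (log2FC 1.855 ± 0.164, adjusted p = 0.000228) and Stat2 (log2FC 1.05 ± 0.107, adjusted p = 0.000378). Of 22 oxidative phosphorylation genes, 0 rose and 17 fell (0 and 19 over the list alone). The median was -0.49 (camera adjusted p = 1.16e-07), or adjusted p = 0.541 with an estimated correlation. Ribosomal protein genes also held less of the counts, at 1.257 and 1.277% in OENr4a3 and 1.593 and 2.002% in OECtrl libraries. Of 25 proliferation genes, 0 rose and 13 fell (0 and 17 over the list alone). The median was -0.48 (camera adjusted p = 9.75e-06), or adjusted p = 0.541 with an estimated correlation. The respiratory chain gene Cox7a2 (log2FC -0.88 ± 0.131, adjusted p = 0.00318) and Cdk1 (log2FC -0.785 ± 0.125, adjusted p = 0.00431) fell. Of 15 macrophage markers, 0 rose and 9 fell (0 and 12 over the list alone). The median was -0.63 (camera adjusted p = 1.67e-06), or adjusted p = 0.481 with an estimated correlation. Of 10 epicardial markers, 0 rose and 6 fell (the same over the list alone). The median was -1.15 (camera adjusted p = 7.96e-08), or adjusted p = 0.481 with an estimated correlation. Of 10 calcium, channel and hormone genes, 6 rose and 1 fell (the same over the list alone). The median was 0.76 (camera adjusted p = 0.0032), or adjusted p = 0.541 with an estimated correlation. Of 23 glycolysis genes, 8 rose and 1 fell (9 and 2 over the list alone). The median was 0.28 (camera adjusted p = 0.00636), or adjusted p = 0.541 with an estimated correlation. The contractile list was not called, and of 12 members, 5 rose and 2 fell (the same over the list alone). The median was 0.715 (camera adjusted p = 0.234). Cdkn2a fell (log2FC -1.51 ± 0.185, adjusted p = 0.00118) and Cdkn1a was not called (log2FC -0.07 ± 0.099, adjusted p = 0.65). In all 3410 genes (1781 up, 1629 down) were called by edgeR, a count that moved without some single libraries, as given below.

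Knockdown of Nr4a3 in 3-month MGT cells at day 7 lowered Nr4a3 from 8.51 ± 0.468 to 0.587 ± 0.221 CPM (log2FC -3.85 ± 0.269, adjusted p = 8.45e-08, n = 2 per group). Interferon, antigen presentation, secretory and proliferation genes were lower, and myofibroblast and some cardiac genes higher, in MGT+shNr4a3 than in MGT+shNT cells. Among the largest rises was the microtubule regulator gene Stmn4 (467 ± 23.8 against 0.622 ± 0.0372 CPM, log2FC 9.54 ± 0.134, adjusted p = 1.54e-13), with the matrix gene Aspn (log2FC 6.44 ± 0.135, adjusted p = 5.99e-12) also up, and the largest falls included Igfbp5 (log2FC -5.25 ± 0.122, adjusted p = 1.1e-11). Of 25 interferon-stimulated genes, 0 rose and 22 fell (0 and 24 over the list alone). The median was -2.16 (camera adjusted p = 3.64e-15), or adjusted p = 0.47 with an estimated correlation. Of 11 antigen presentation genes, 1 rose and 8 fell (the same over the list alone). The median was -1.17 (camera adjusted p = 4.07e-07), or adjusted p = 0.47 with an estimated correlation. Oas2 (log2FC -3.58 ± 0.136, adjusted p = 4.39e-10) and the class I gene H2-K1 (log2FC -3.88 ± 0.106, adjusted p = 3.42e-11) fell. Of 26 senescence secretory genes, 5 rose and 17 fell (the same over the list alone). The median was -1.54 (camera adjusted p = 1.3e-08), or adjusted p = 0.47 with an estimated correlation. Of 16 targets of NF-kappaB, 2 rose and 9 fell (the same over the list alone). The median was -1.505 (camera adjusted p = 0.00302), or adjusted p = 0.47 with an estimated correlation. The chemokine gene Ccl2 (log2FC -4.35 ± 0.113, adjusted p = 2.65e-11) fell. Of 25 proliferation genes, 0 rose and 24 fell (0 and 25 over the list alone). The median was -0.83 (camera adjusted p = 3.46e-06), or adjusted p = 0.47 with an estimated correlation. Of 15 myofibroblast genes, 14 rose and 0 fell (the same over the list alone). The median was 1.49 (camera adjusted p = 1.11e-13), or adjusted p = 0.47 with an estimated correlation. Mki67 (log2FC -0.58 ± 0.087, adjusted p = 9.02e-05) fell and Postn (log2FC 3.55 ± 0.108, adjusted p = 7.61e-11) rose. Of 20 contractile genes, 10 rose and 2 fell (11 and 2 over the list alone). The median was 0.84 (camera adjusted p = 0.00524), or adjusted p = 0.47 with an estimated correlation. Of 17 calcium, channel and hormone genes, 7 rose and 3 fell (the same over the list alone). The median was 0.19 (camera adjusted p = 0.000176), or adjusted p = 0.47 with an estimated correlation. Actc1 (log2FC 3.73 ± 0.15, adjusted p = 6.41e-10) and the natriuretic peptide gene Nppa (log2FC 4.82 ± 0.132, adjusted p = 3.42e-11) rose. The factor genes Mef2c (log2FC -0.56 ± 0.109, adjusted p = 0.000776) and Gata4 (log2FC -0.37 ± 0.085, adjusted p = 0.0024) fell, and Cdkn2b rose (log2FC 0.90 ± 0.144, adjusted p = 0.000145). The edgeR test called 9841 genes (5032 up, 4809 down).

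Genes called between 24-month and neonatal CFs were then followed into the other libraries, as sets of the 200 with the smallest p in each direction (n = 2 libraries per group throughout). Genes higher at 24 months were more often higher than lower with Nr4a3 overexpressed (96 rose and 22 fell of 197, median log2FC 0.42, camera adjusted p = 8.68e-16) and mostly lower with Nr4a3 knocked down (23 rose and 136 fell of 196, median log2FC -1.11, camera adjusted p = 4.12e-26). Genes lower at 24 months were not called as a set with overexpression (59 rose and 43 fell of 200, median log2FC 0.06, camera adjusted p = 0.426) and were higher with knockdown (110 rose and 43 fell of 191, median log2FC 0.54, camera adjusted p = 1.2e-12). The set higher at 24 months was lower in MGT than in LacZ cells in neonatal (13 rose and 75 fell of 199, median log2FC -0.32, camera adjusted p = 6.1e-19), 3-month (19 rose and 123 fell of 199, median log2FC -0.49, camera adjusted p = 2.36e-26) and 18-month cells (21 rose and 54 fell of 199, median log2FC -0.19, camera adjusted p = 0.000328, or adjusted p = 0.31 with an estimated correlation). The set lower at 24 months was higher in MGT cells at 3 months (92 rose and 25 fell of 199, median log2FC 0.33, camera adjusted p = 2.92e-26) and 18 months (93 rose and 23 fell of 199, median log2FC 0.31, camera adjusted p = 9.82e-30), with a median near 0 in neonatal cells (56 rose and 32 fell of 199, median log2FC 0.04, camera adjusted p = 0.000496, or adjusted p = 0.12 with an estimated correlation). Calls without a second p held with an estimated correlation. Genes moved by overexpression were not called as sets with knockdown. Of the set that rose with overexpression 65 rose and 77 fell of 186, median log2FC -0.22, camera adjusted p = 0.274, and of the set that fell 45 rose and 58 fell of 157, median log2FC -0.15, camera adjusted p = 0.289. Neither had an unadjusted p under 0.05.

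Among single reprogrammed cells, n = 1 library per age allowed no test between ages, and intervals are exact 95% intervals of counting alone. Cardiomyocyte-like cells made up 32.8% (1254 of 3828, 31.3 to 34.3%) of neonatal and 0.243% (14 of 5773, 0.133 to 0.407%) of 24-month cells, and in a run on cells with at least 1000 genes these shares were 41.4% (1148 of 2775, 39.5 to 43.2%) and 0.459% (20 of 4355, 0.281 to 0.708%). A low-depth cluster (median 1729 UMIs) held 300 of the 1254 neonatal cells. Macrophage-like cells made up 5.22% (200 of 3828, 4.54 to 5.98%) and 12.3% (712 of 5773, 11.5 to 13.2%), endothelial-like cells 1.93% (74 of 3828, 1.52 to 2.42%) and 0.329% (19 of 5773, 0.198 to 0.513%), and clusters left unnamed 60.1% (2300 of 3828, 58.5 to 61.6%) and 87.1% (5028 of 5773, 86.2 to 87.95%). An unnamed cluster of 2 neonatal and 1408 aged cells expressed Mfap5 and Ccl8, and another of 12 neonatal and 1408 aged cells Saa3, Hp and Cxcl5. From neonatal to aged cells Tnnt2 went from 4119 to 72.9 CPM (ratio 0.0177, 0.0174 to 0.018), the myoglobin gene Mb to a ratio of 0.0009995, and Myh6, at 101 CPM in neonatal and without a UMI in aged cells, was at least 5112-fold lower. Mmp3 went from 34.7 to 2436 CPM (ratio 70.1, 68 to 72.3). Nr4a3 went from 2.23 to 7.49 CPM (ratio 3.36, 2.94 to 3.85), and was at 3.9 CPM in neonatal cardiomyocyte-like, 1.28 CPM in neonatal unnamed and 8.25 CPM in aged unnamed cells. The unnamed cells of the ages lay mostly in different clusters, and many were of low depth. Of 2 low-depth clusters, 1 held 1308 neonatal and 85 aged cells (median 2252 UMIs) and the other 19 neonatal and 1529 aged cells (median 1690.5 UMIs). A Nr4a3 UMI was found in 4.31% of neonatal and 9.32% of aged cells, against 1.0% and 0.421% of macrophage-like cells. A Tnnt2 UMI was found in 94.7% and 14.4% of all against 74.5% and 4.78% of macrophage-like cells. Median depth was 13960 and 20771 UMIs over all cells and 27280 and 20240 UMIs in macrophage-like cells. With cells thinned to 5000 UMIs the Nr4a3 shares were 1.41% and 3.605% of all against 0.621% and 0% of macrophage-like cells, and the Tnnt2 shares 86.5% and 7.24% against 33.5% and 1.299%. Free RNA and doublets, which were not removed, were not separated from expression in these shares.

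**Figure D4:**
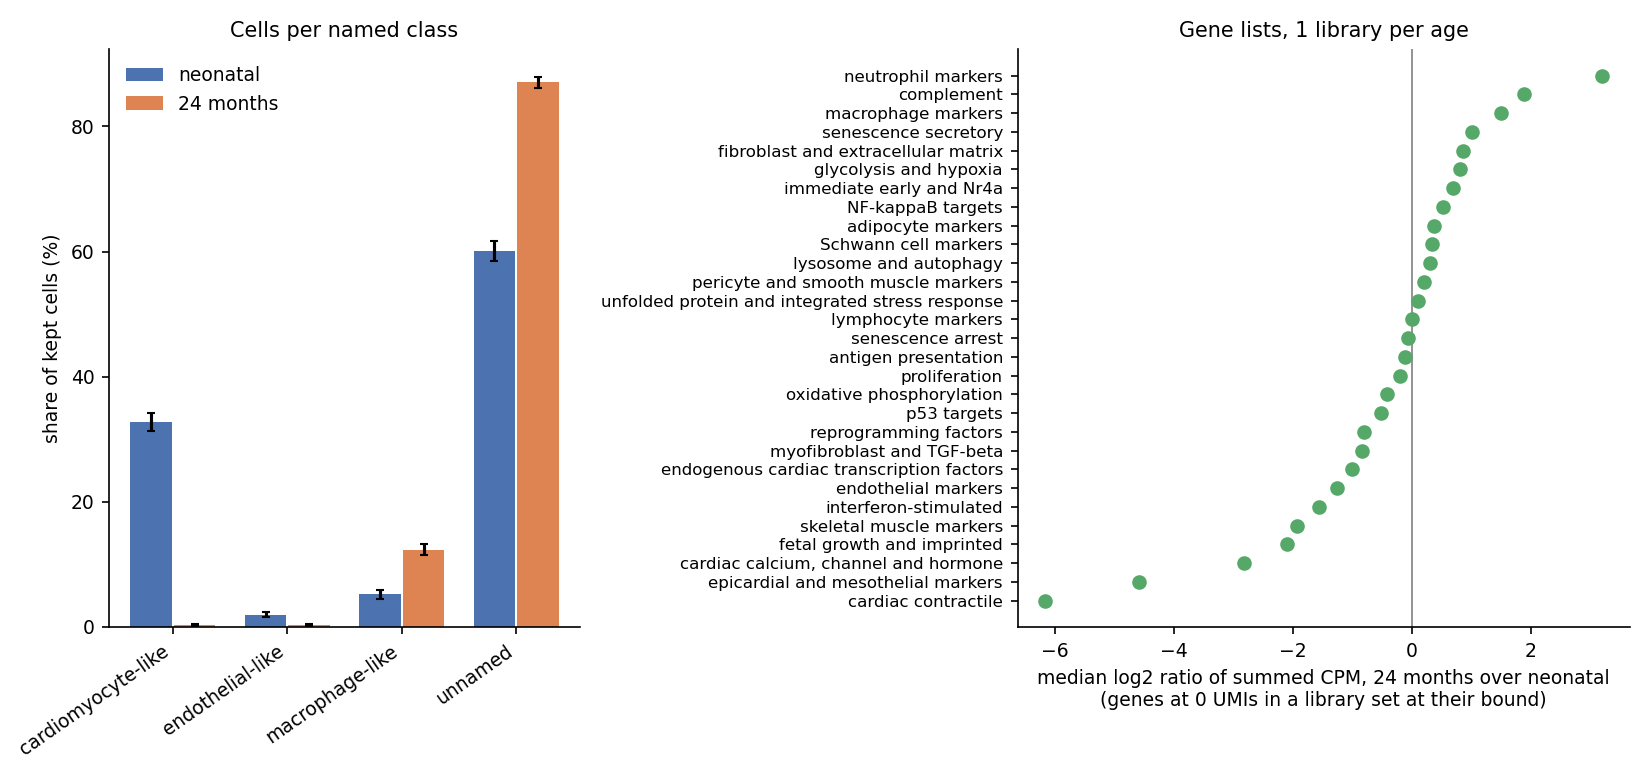
Shares of cell classes among neonatal and 24-month single cells with exact 95% intervals, and gene list medians of the aged over neonatal ratio, with genes at 0 UMIs at their bound.

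By list, aged single cells (n = 1 library per age) had lower contractile genes (0 higher and 19 lower, median log2 ratio -4.66, or -6.16 with bounds), calcium, channel and hormone genes (2 higher and 16 lower, median log2 ratio -1.33, or -2.82 with bounds), interferon-stimulated genes (0 higher and 23 lower, median log2 ratio -1.54, or -1.56 with bounds) and fetal growth genes (1 higher and 15 lower, median log2 ratio -1.66, or -2.10 with bounds). Epicardial (0 higher and 10 lower, median log2 ratio -2.865, or -4.58 with bounds) and endothelial markers (4 higher and 8 lower, median log2 ratio -1.05, or -1.26 with bounds) were lower too, and at Leiden resolution 1.0 an epicardial- or mesothelial-like class held 69 neonatal and 0 aged cells. Higher in aged cells were complement (9 higher and 1 lower, median log2 ratio 1.89, or 1.90 with bounds), matrix (20 higher and 4 lower, median log2 ratio 0.86, or 0.86 with bounds), senescence secretory (24 higher and 7 lower, median log2 ratio 0.60, or 1.01 with bounds) and macrophage genes (16 higher and 0 lower, median log2 ratio 1.32, or 1.495 with bounds). Isg15 went from 568 to 251 CPM (ratio 0.442, 0.436 to 0.447), and the complement gene C3 to a ratio of 35.3 (33.3 to 37.5). Of the factors, Mef2c went from 213 to 87.7 CPM (ratio 0.411, 0.403 to 0.42), Gata4 from 68.8 to 42.2 CPM (ratio 0.613, 0.593 to 0.633) and Tbx5 from 5.64 to 3.23 CPM (ratio 0.573, 0.509 to 0.644). Cdkn1a had a ratio of 0.604 and Mki67 of 1.49, while Cdkn2a, at 0.654 from summed counts, was at 1.027 as a mean over cells. The libraries also differed in sex signal, with Xist at 169 CPM in neonatal and 0.0329 CPM in aged cells.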

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

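The tests of the difference between ages in the MGT effect were planned, and the tests of explanations were all chosen after the results were seen. The MGT effect differed between 3-month and neonatal cells for 605 genes, between 18-month and neonatal cells for 461 genes and between 18-month and 3-month cells for 383 genes, by an edgeR test of the difference itself with n = 2 libraries per group. All values in this and the next paragraph are log2 differences of the MGT effect. For 3 months against neonatal they were Abi3bp -3.15, Arhgap20 -1.75, Msln 5.35, Mx2 -1.52, Tnnt2 4.74 and Upk1b 6.03, and a fitted 8.45 for Myl7, which had no read in 3-month LacZ cells, so that its size is not set by the data. For 18 months against neonatal they were Abi3bp -3.87, Actc1 5.70, Aqp1 -1.485, Arhgap20 -1.56, Msln 4.335, Myl7 5.71, Rgs2 -1.59, Tbx5 2.01, Tnnt2 4.32 and Upk1b 4.63, and for 18 against 3 months Ctsc -1.34, Pdlim3 3.49, Serpina3i 2.73 and Vgf -1.36. The sizes for Actc1 and for Myl7 at 18 months are loose as well, as Actc1 had 2 and 1 counts in 3- and 18-month LacZ cells and Myl7 had 1 count in 18-month LacZ cells. Calls that were lost without some single library were Ackr3 -1.54, Actc1 4.88, Ifit3 -1.98, Mef2c 0.93 and Tbx5 1.36 for 3 months against neonatal, Cdkn2b 0.97 and Ly6c1 -1.72 for 18 months against neonatal, and Cmpk2 2.31, Flt1 -1.825, Gbp5 2.62, Rsad2 2.64, Sprr2h -1.49 and Upk1b -1.39 for 18 against 3 months. The Serpina3i value ranged from 1.80 to 5.44 with single libraries left out.

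Among the gene lists, the median difference for 3 months against neonatal was antigen presentation -0.305, contractile 0.95, endothelial 0.985, epicardial 2.82, interferon-stimulated -0.67, macrophage 0.54 and reprogramming factor 0.93. For 18 months against neonatal it was antigen presentation 0.44, contractile 1.10, complement 0.79, endothelial 0.885, epicardial 2.01, fibroblast and matrix 0.33, interferon-stimulated 0.13, macrophage 0.35 and reprogramming factor 0.65, and for 18 against 3 months antigen presentation 0.83, complement 0.775, fibroblast and matrix 0.32 and interferon-stimulated 0.84. Each was called by camera at the preset correlation. With an estimated correlation only the epicardial list kept its call, in both comparisons with neonatal cells.

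Interferon-stimulated genes were higher in adult than in neonatal CFs and lower in the oldest than in neonatal MGT and LacZ cells. With an estimated correlation the list had adjusted p = 0.0328, 0.119 and 0.0508 in CFs at 3, 12 and 24 months and 0.01 and 0.0065 in MGT and LacZ cells at 18 months. More macrophages in adult cultures would raise macrophage markers, but the median of that list was -1.32 at 3 months against neonatal CFs, which argues against them. Sex does not explain it either, since the interferon median was 3.48 between 24-month and neonatal CFs, which both expressed Xist, and -2.61 between 18- and 3-month MGT cells, which both lacked it. A difference between culture or library batches of the age groups could account for it, because the interferon median for 3 months against neonatal cells was 4.01 in CFs but 0.20 in LacZ cells of another experiment. At 18 months it was -3.64 in LacZ cells, without factors, against 3.48 in 24-month CFs. LacZ cells were also transduced and CFs were not, so this contrast does not separate batch from the vector. An effect of age itself stays open and was not tested.

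The interferon list was higher with Nr4a3 overexpressed and lower with Nr4a3 knocked down. Neither call held, at camera adjusted p = 0.481 and 0.47 with an estimated correlation, a setting that is strictest with so few libraries. A single library does not account for the medians, which stayed at 1.07 or more with overexpression and at -1.875 or less with knockdown with each library left out. The macrophage median was -0.63 with overexpression (adjusted p = 0.481 with an estimated correlation), which argues against more macrophages there. Fewer macrophages with knockdown cannot be told apart from an Nr4a3 effect, because the macrophage median was -0.86 and not called (camera adjusted p = 0.198). A response to the vectors that does not need Nr4a3 cannot be told apart from an Nr4a3 effect. Genes higher with overexpression were not called as a set in the knockdown (camera adjusted p = 0.274), but the cells were neonatal CFs without MGT at day 10 and 3-month MGT cells at day 7, so this decides nothing. An effect of Nr4a3 on these genes stays open.

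Contractile genes were lower in adult than in neonatal cultures, with and without MGT. With an estimated correlation the list had adjusted p = 0.0594, 0.101 and 0.0856 in CFs at 3, 12 and 24 months, 0.12 and 0.21 in MGT cells and 0.0486 and 0.0881 in LacZ cells at 3 and 18 months. Cardiomyocytes or their RNA carried into the neonatal cultures could account for this, because the contractile median was already -2.44 in 3-month against neonatal LacZ cells, which received no factors. In bulk MGT cells lower levels of all 3 factors do not, since Tbx5 had a log2FC of 0.22 in 3-month against neonatal cells. Lower Gata4 (287, 237 and 233 CPM in neonatal, 3- and 18-month cells) or Mef2c (199, 207 and 165) stays open. In the single cells they could, as the ratio of aged over neonatal was 0.411 for Mef2c, 0.613 for Gata4 and 0.573 for Tbx5. The single-cell libraries share the doubt about carry-over, as a neonatal cardiomyocyte-like cell can be a carried-over cardiomyocyte or a reprogrammed fibroblast. A lower response of adult fibroblasts was not tested apart from carry-over.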

How the results depend on the processing

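The alternatives were planned, except the crossed block and the fit without genes of the X and Y chromosomes, which were chosen after the data were seen, and the cause of each change named here was not tested. All 19 counts of called genes stayed within 1.5 times with RLE size factors, without the filter on low counts and without genes of the X and Y chromosomes, and 16 did with DESeq2. DESeq2 called 3091, 1898 and 1971 genes for CFs at 12 against 3, 24 against 3 and 24 against 12 months. A fit to only the groups compared called 1977 and 1798 genes for MGT against LacZ in neonatal and 3-month cells and 882 for the difference of the MGT effect at 18 months against neonatal, and kept 14 counts. Of the named genes, 1057 values kept their call with RLE and 1 lost it, and 1037 kept, 17 lost and 2 gained it with DESeq2. Leaving out single libraries, where the lone library of a group is assumed to vary like the other groups, kept 55 counts and moved 33. The lowest and highest count was 1872 to 2597 for CFs at 24 against 12 months, 688 to 1037, 1732 to 4476 and 1452 to 2136 for MGT against LacZ in neonatal, 3-month and 18-month cells, 363 to 1760, 241 to 372 and 159 to 1012 for the differences of the MGT effect, 2758 to 3273 and 1367 to 2262 for MGT cells at 3 months against neonatal and 18 against 3 months, and 1197 to 7704 for OENr4a3. For named genes 4464 such values kept their call, 247 lost it, 31 gained one and 26 moved. Of 235 list calls in the 17 planned comparisons, 58 remained with an estimated correlation.

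A replicate block kept all 19 counts and gave 239 list calls in the 17 planned comparisons, adding among the described lists the contractile genes in CFs at 24 against 12 months (adjusted p = 0.0432). Replicate numbers did not pair the libraries, as the deviations of same-numbered libraries had correlations from -0.189 to 0.201, and a crossed replicate block in the overexpression, where it was -0.18, called 4452 genes.

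In the single cells, 119 values stayed the same with all barcodes, 58 with TMM scaling and 25 as a mean over cells, where 60 and 88 moved past their counting interval. Ratios of aged over neonatal that changed side were Jund with all barcodes (1.003), Jund and Ndn with TMM scaling (1.022 and 1.016), and as a mean over cells Cd79b 1.45, Cdkn2a 1.027, Jund 1.087, Lipe 0.7802, Ms4a1 0.2157, Sparc 0.975 and Tapbp 1.012. Thinning cells to 5000 UMIs moved 29 of the shares of cells with a UMI, Leiden resolution 1.0 moved 3 class shares and a minimum of 1000 genes moved 5. Depth limits the genes with few counts. Between 2 groups their folds are given as bounds or with counting intervals, but differences of the MGT effect are fitted values without them.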

Other observations

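The contrasts between ages in LacZ control cells were chosen after the data were seen. LacZ cells, which carried no reprogramming factor, had higher secretory and lower contractile and fetal growth genes at both adult ages than in neonatal cells, and lower interferon-stimulated genes at 18 months (n = 2 libraries per group). The mesothelial gene Msln (log2FC -7.14 ± 0.163 and -6.62 ± 0.154, adjusted p at most 4.92e-21) and the fetal gene Plagl1 (log2FC -3.74 ± 0.136 and -4.03 ± 0.14, adjusted p at most 2.08e-17) fell at 3 and 18 months, and Mmp3 (log2FC 5.98 ± 0.126 and 4.75 ± 0.12, adjusted p at most 2.42e-19) rose. Of 17 contractile genes, 0 rose and 10 and 13 fell (0 up with 12 and 14 down over the list alone), with medians of -2.44 and -2.785 (camera adjusted p = 7.33e-14 and 3.15e-10, and adjusted p = 0.0486 and 0.0881 with an estimated correlation). The alpha myosin gene Myh6, without a read in 3-month LacZ cells, was at least 88.2-fold lower there. Of 25 interferon-stimulated genes, 7 and 0 rose and 2 and 25 fell (the same over the list alone), with medians of 0.20 and -3.64 (camera adjusted p = 0.139 and 7.9e-79) and with Bst2 (log2FC -3.37 ± 0.116, adjusted p = 1.25e-16) at 18 months. Of 16 fetal growth genes, 1 rose and 15 fell each time (the same over the list alone), with medians of -2.03 and -2.26 (camera adjusted p = 2.47e-26 and 1.24e-29), and of 31 senescence secretory genes, 20 and 19 rose and 6 and 7 fell (21 and 20 up with 6 and 7 down over the list alone), with medians of 1.48 and 1.14 (camera adjusted p = 2.08e-15 and 3.89e-07, and adjusted p = 0.0128 and 0.0604 with an estimated correlation). Of 25 proliferation genes, 10 and 18 rose and 1 and 0 fell (the same over the list alone), with medians of 0.20 and 0.41 (camera adjusted p = 0.0142 and 2.97e-05, and adjusted p = 0.482 and 0.28 with an estimated correlation). Nr4a3 rose as well (log2FC 2.15 ± 0.226 and 1.86 ± 0.232, adjusted p = 1.26e-07 and 1.4e-06), and its family member Nr4a1 (log2FC 2.59 ± 0.17, adjusted p = 2.97e-07) rose at 3 months. The edgeR tests called 5054 genes (2464 up, 2590 down) and 5729 genes (2737 up, 2992 down).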
